A study of Homo sapiens with 4 samples.

How the data were processed

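Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where the transcription factor SPIB sits on DNA in H1703 cells. H1703 is an established human lung squamous carcinoma cell line. SPIB is an ETS-family transcription factor known mainly from B cells and plasmacytoid dendritic cells. The cells overexpressed SPIB, and the antibody was anti-FLAG M2, per the labels. The 4 libraries were 1 SPIB ChIP and 1 input (sonicated DNA without immunoprecipitation) from attached cells, and 1 of each from suspended cells. The groups were taken from the condition and antibody labels. The treatment protocol in the labels names 24 h of suspension for every library, including those labelled attached, and the condition label was used to tell them apart.

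Peaks were called by the authors with MACS 1.4.2, separately for each ChIP library against the input of its own condition, per the file headers. The headers give a p cutoff of 1e-05, a band width of 200 bp and a model fold range of 10 to 30. They also give local background windows of 1 and 10 kb, 1 tag kept per position and a tag size of 50 bp. The fragment length modelled by MACS was 58 bp (attached) and 63 bp (suspended), close to the tag size in both conditions. What this does to the called peaks, their summits and their widths was not tested. The larger library of each pair was scaled to the smaller one, per the file headers. Coordinates are on hg38, per the submitters' processing notes. The aligner is not given in the sources used here. Each deposited list gives tags per peak as a count of ChIP tags in the region, and these counts are not normalized. Fold enrichment is the authors' ratio of ChIP tags to the local background. The authors' score is minus 10 times log10 of the MACS p-value, read from the column's place and its lowest value of 50, because the column name was lost to a spreadsheet error. The authors' false discovery rate (FDR) is a percent, which MACS 1.4.2 obtains by calling peaks again with ChIP and input exchanged. Fold, score and FDR are the authors' values, and were used only to describe, rank or filter peaks within a list.

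After filtering, the ChIP libraries held 21108364 tags (attached) and 20766909 tags (suspended), and the inputs 15878452 and 21437074 tags, per the file headers. Depth-scaled tags are tags divided by the filtered ChIP tags of the library. The median peak held 18 tags in attached and 15 tags in suspended cells, so tags of single peaks are given with exact Poisson 95% intervals where they are compared. Poisson and binomial intervals cover counting error only. With 1 library per group there are no replicates, so no p-value between conditions is given.

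Peaks were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plotted with matplotlib 3.10.9. A peak was called shared where it overlapped a peak of the other list by at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals. Overlap was set beside 1000 seeded placements of the suspended peaks on their own chromosomes. Placement ran from the first to the last annotated gene of a chromosome and did not avoid assembly gaps. Genes came from a RefSeq table for GRCh38.p14, the assembly that hg38 names, with 59679 genes on chromosomes 1 to 22, X and Y. The table gives gene spans without strand, exons or UTRs. Therefore the planned promoter class became a summit within 1 kb of either end of a gene, the planned flank of 5 kb was taken on both sides, and exon, intron and UTR classes were not assigned.

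For gene lists, the members with a peak from 5 kb before to 5 kb after the gene were counted. The count was set among 10000 seeded random lists of the same size drawn from 20037 protein-coding genes matched on gene span in 20 bins. The percentile is the share of random lists with fewer such members, with ties shared equally, and describes these 2 libraries. A list is called outside the random range where its percentile lay below 2.5 or above 97.5. Because ties are shared, a count equal to an end of the central 95% of random lists can be called outside. The 14 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, and all list members were found in the table. The rule named the 10 peaks of highest fold in each list, the 10 shared peaks of highest suspended fold, each list member with a peak within 1 kb of a gene end, up to 4 other members per list by fold, and SPIB and SNAP47 whatever their values. A gene was assigned where the summit lay in it or within 5 kb, and otherwise the nearest gene was given. A few genes that the rule names are not reported here. The 12 gene families and the neuronal and glial lists of the closing section were chosen after seeing the data, as was the choice to test FDR limits, peak width at shared sites, locally moved peaks, gene starts marked by divergent transcripts, and gene lists outside crowded windows.

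The gene-end count and the list procedure were run on simulated data. With 30% of the peaks planted at gene ends (the lower coordinate of the span), the expected share was 34.2% and the recovered share 34.2% for the 8981 suspended peaks on chromosomes 1 to 22, X and Y, and 35.5% and 35.3% for the 453 attached peaks. The expected share was computed from the same simulated peaks, so both shares had to agree apart from rounding. Their agreement is therefore no test of the count or of random placement. Over 200 random lists of 40 genes the mean percentile was 53.2 (suspended) and 48.6 (attached), where 50 is the chance value. A list in which 62.9% (suspended) or 20% (attached) of the genes were given a peak reached percentile 100. Smaller planted enrichments were not simulated. The planned search for 7 sequence motifs was not run, because no genome sequence was used here.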

Results

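SPIB-bound DNA was mapped by ChIP-seq in SPIB-overexpressing H1703 lung squamous carcinoma cells that were either attached or kept in suspension. Each condition had 1 ChIP library and 1 input library, so the comparisons below describe these libraries and have no replicate check. The filtered ChIP libraries were close in depth, with 21108364 tags from attached cells and 20766909 from suspended cells. The input of the attached cells was smaller, with 15878452 tags against 21437074. The comparison the design implies is between the SPIB sites of attached cells and those of cells that have lost contact with their substrate, and the gene lists were chosen around autophagy, cell survival and adhesion for that reason.

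The first comparison concerned the number and strength of SPIB peaks. The authors' list held 462 peaks in attached cells and 9024 in suspended cells, 19.5 times as many. Peaks covered 134.91 kb in attached and 2982.11 kb in suspended cells, and held 0.0494% and 0.919% of the filtered ChIP tags. Single peaks were alike in size, with a median width of 254 bp and 252 bp and a mean of 22.6 and 21.1 tags per peak. Among protein-coding genes, 372 of 20037 (1.86%) had a peak in the gene or within 5 kb of it in attached cells, and 5733 (28.6%) did in suspended cells. The authors' FDR was 100% for 305 attached peaks (66.0%), and at most 6.42% for every suspended peak. At an FDR of at most 5%, 25 attached and 6933 suspended peaks remained. At a score of at least 64.08, the attached list held 157 peaks and the FDR implies 154 peaks with ChIP and input exchanged, whereas the suspended list held 3112 peaks against 80 exchanged ones. At that score exchanged peaks were about as many as attached peaks, and a site absent from the attached list is not shown to be unbound there.

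Several of the peaks of highest fold lay in or near genes known for their work in neurons. In attached cells the authors' fold was highest in NPAS4, an activity-dependent neuronal transcription factor, at chromosome 11, 66421548 to 66422000 (hg38), with a fold of 53.05 and 89 tags (95% Poisson interval 71.5 to 109.5). Others of the 10 highest in attached cells lay in or beside LRRC37A2 (fold 37.77), the homeobox gene NKX1-1 (36.19), the serotonin receptor gene HTR5A (34.48), XKR7 (31.83) and the potassium channel gene KCNH7 (31.76). Of the remaining 4, 1 lay in or within 5 kb of F8, H2AB1 and F8A1 (35.29), and 3 lay far from genes, with PBX3 (43.1), PTPRU (34.48) and GAD2 (31.76) nearest. In suspended cells the highest fold was 49.16, at a site on chromosome 9, 126082685 to 126082986, 115505 bp from the end of PBX3 and called in both lists. The peak in SNAP25, a synaptic vesicle fusion protein gene, followed among sites on assembled chromosomes, with a fold of 40.05 and 40 tags (28.6 to 54.5) at chromosome 20, 10219480 to 10219817. Further sites lay in or near CEACAM20 (36.18), the postsynaptic scaffold gene SHANK2 (33.2), the neural adhesion gene L1CAM (31.15) and SCRT1 (29.13), a neuronal repressor gene. The nearest genes of 3 others were ERC2 (37.26), CWH43 (31.04) and ZNRF4 (30.18), and 1 lay on an unplaced sequence (42.23).

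The second comparison asked how far the attached sites recur in suspended cells. Of the 462 attached peaks, 210 (45.5%, Clopper-Pearson 95% interval 40.8 to 50.1) overlapped a suspended peak by at least 1 bp, and 212 of the 9024 suspended peaks (2.35%) overlapped an attached one. Random placement of the suspended peaks gave a mean of 0.249% of attached peaks and at most 1.32% in 1000 placements. The overlap followed the authors' FDR. All 37 attached peaks with an FDR of at most 10% were in the suspended list (100%, lower bound 90.5%), against 88 of the 305 with an FDR of 100% (28.9%, 23.8 to 34.3). Among suspended peaks, 24.6% of the top 5% by score were shared, and 0.377% of the lower 4512. The shared sites of highest suspended fold lay in or within 5 kb of SNAP25, SHANK2, L1CAM, SCRT1, the splicing factor gene SRRM3 (29.02), the heparan sulfate enzyme gene HS3ST2 (28.3) and the netrin receptor gene UNC5A (28.25), and 3 lay further from genes, with ERC2 (26387 bp away), PBX3 (115505 bp) and CWH43 (647670 bp) nearest.

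**Figure D1:**
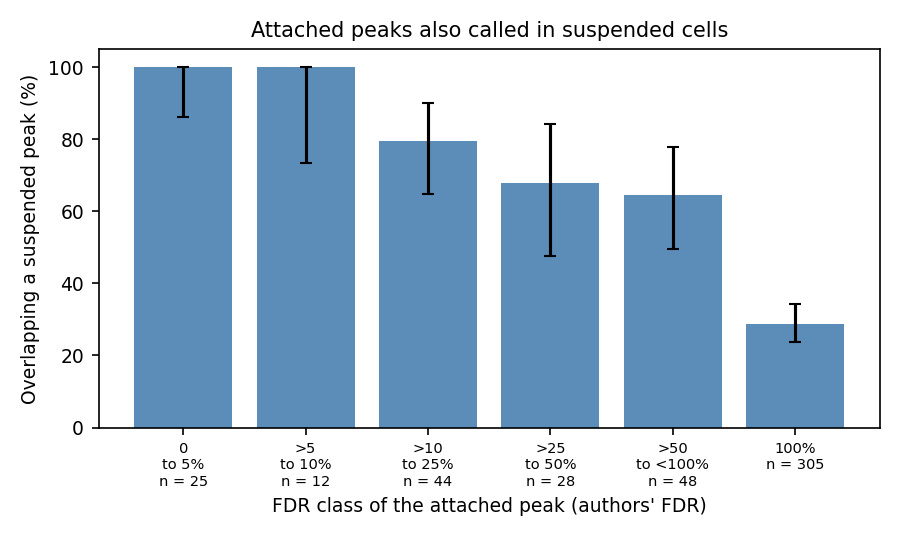
Share of attached peaks that overlap a suspended peak (y axis, percent) by the authors' FDR of the attached peak (x axis, with the number of peaks). Bars are shares and whiskers Clopper-Pearson 95% intervals, and the share runs from 100% in the lowest class to 28.9% at an FDR of 100%.

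At the 210 shared sites the called peak held more tags in the suspended list and was more often the wider one. The median ratio of depth-scaled tags (tags divided by the filtered ChIP tags of the library), suspended to attached, was 1.36 (interquartile range 1.08 to 1.76, bootstrap 95% interval over sites 1.29 to 1.42), and it was above 1 at 170 sites. The suspended peak was the wider at 151 of these sites and the attached one at 58, with median widths of 378.5 and 324 bp. Per bp of peak the median ratio was 1.104 (1.06 to 1.15), above 1 at 140 sites. At the 103 sites where the narrower peak was at least 80% as wide as the other the ratio of tags was 1.19 (1.12 to 1.28). At the 59 where the suspended peak was no wider it was 0.987 (0.923 to 1.08), but per bp it was 1.19 (1.11 to 1.31), above 1 at 48 of them. Those 59 were picked on width, with a median width ratio of 0.876, so their lower tag count partly follows from the choice. Both splits were chosen after the first ratios were seen. SNAP25 had 16 tags (Poisson 95% interval 9.15 to 26.0) in the attached and 40 (28.6 to 54.5) in the suspended peak. L1CAM had 28 (18.6 to 40.5) and 59 (44.9 to 76.1). Their ratios of 2.54 and 2.14 lie above the median. The suspended peak was also wider, 338 against 244 bp at SNAP25 and 457 against 279 bp at L1CAM, so these tag counts are not like for like. The lowest and highest ratios were picked out after the values were seen. The lowest, 0.449, was at RNVU1-27, with 43 tags (31.1 to 57.9) in the attached and 19 (11.4 to 29.7) in the suspended peak. At the highest, 5.66, the nearest gene was CWH43, with 14 tags (7.65 to 23.5) in 252 bp in the attached list. The suspended peak there held 78 tags (61.7 to 97.3) in 584 bp.

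**Figure D2:**
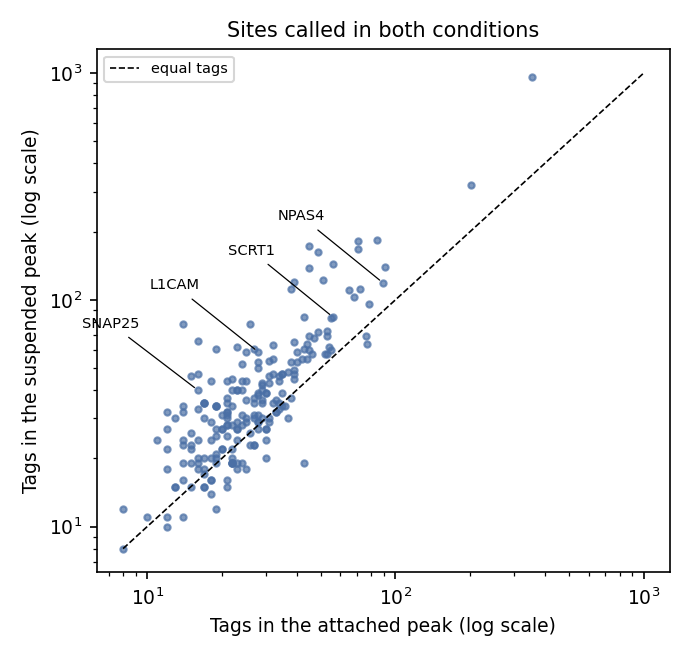
Tags in the attached peak (x axis, log scale) and in the suspended peak (y axis, log scale) at each of the 210 sites called in both lists, 1 point per site, with NPAS4, SNAP25, L1CAM and SCRT1 named. The dashed line marks equal tags, and more points lie above it than below.

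The third comparison concerned the position of the peaks relative to genes. Peaks lay close to gene ends in both conditions. In attached cells 38.4% of 453 summits (33.9 to 43.1) were within 1 kb of a gene end, and in suspended cells 36.4% of 8981 (35.4 to 37.4). Random placement gave a mean of 6.83% and 6.79%, so the observed shares were 5.62 and 5.36 times those. A further 36.2% of attached and 42.9% of suspended summits lay inside genes, and 25.4% and 20.7% between genes. The table of genes has no strand, but for 528 genes a divergent transcript marks the start, and there 91 genes (17.2%, 14.1 to 20.7) had a suspended peak within 1 kb of the start and 1 (0.189%) at the other end.

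The share near gene ends rose with peak strength. In suspended cells it was 24.7% in the lowest 25% of scores and 64.3% (59.7 to 68.8) in the top 5%. In attached cells it was 51.9% (44.9 to 58.9) of the shared peaks and 27.1% (21.7 to 33.1) of those not shared, where random placement gave 6.55%. The overall shares in both conditions are not a like-for-like comparison, since the 462 suspended peaks of highest score had 64.7% of summits near a gene end.

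**Figure D3:**
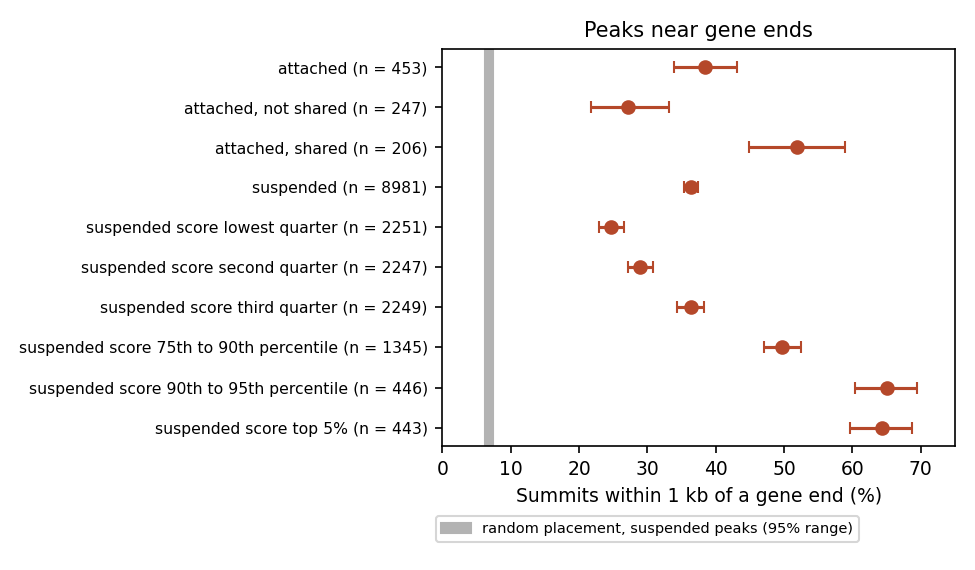
Share of peak summits within 1 kb of a gene end (x axis, percent) in the attached and suspended lists, in shared and not shared attached peaks and in classes of the suspended score. Points are shares with Clopper-Pearson 95% intervals and the grey band is the central 95% of random placements of the suspended peaks, and the suspended share climbs from 24.7% to 64.3% across the score classes, with 65.0% between the 90th and 95th percentiles.

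The fourth comparison asked which groups of genes held peaks. In suspended cells the autophagy receptor genes lay above the random range at gene ends, with 8 of 18 members, where random lists had a mean of 2.82. These were SQSTM1, which encodes the cargo receptor p62, NBR1, NCOA4 (the ferritin receptor), BNIP3 and PHB2 (both tied to removal of mitochondria), RETREG1 and SEC62 (both tied to removal of endoplasmic reticulum) and WDFY3. RTN3 had a peak further inside. Random lists were matched on gene span but not on gene activity, which was not measured here. Cytoplasmic ribosomal protein genes, a family chosen after seeing the data, also lay above the range at gene ends (24 of 73 members, random mean 9.25). An excess at gene ends was therefore not particular to autophagy genes. Counted over the whole gene and 5 kb around it, 9 of 18 receptors had a peak, at percentile 95.04 of random lists and so within the random range. Outside the windows most crowded with peaks, 5 of the 12 receptors left had a peak at a gene end (98.7). MTOR and AMPK signalling genes had a peak at a gene end in 11 of 38 members (percentile 99.1, random mean 5.31) and over the whole gene in 14 (80.4). Outside crowded windows this count was 6 of 28 at a gene end (90.2), within the random range. They included PRKAA1 and the AMPK subunit genes PRKAG1 and PRKAG2, TSC1, AKT1, AKT1S1, RPTOR, MLST8, EIF4EBP1 and DDIT4, while AKT2, CAMKK2 and STK11 had peaks elsewhere in the gene. In attached cells no receptor gene had a peak, where random lists had a mean of 0.343 (percentile 35.2), so that 0 is within the random range. PRKAA1, MLST8, SESN1 and RICTOR had one, 4 of 38 members (99.6).

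Autophagosome formation genes had a peak in 18 of 40 members in suspended cells (percentile 96.7, random mean 12.5), within the random range, though above it (98.5) against random lists not matched on gene span. Peaks lay at a gene end of ATG4B, ATG7, ATG12, NRBF2, ULK1, GABARAP and WIPI1, and elsewhere in or within 5 kb of AMBRA1 (fold 17.6), PIK3R4, ATG10 and VMP1, among others. In attached cells 3 members had one, namely ULK1, UVRAG and GABARAP (97.8). Genes of autophagosome-lysosome fusion had a peak in 12 of 34 members in suspended cells (72.6), among them at the ends of VPS41, YKT6, RAB2A, VPS33A, VPS33B, EPG5 and VPS16, and elsewhere in or within 5 kb of RUBCN, SNAP47, VPS11 and TECPR1. LAMP1 was the member with an attached peak. Lysosome genes had fewer peaks than random lists, in 11 of 71 members against a mean of 20.3 (0.505). CTSV, TPP1, TPCN2, NPC2, GLA and ATP6V1A had one at a gene end, and ATP6V1B1, ATP6V1E1, MANBA and MCOLN1 elsewhere in or within 5 kb of the gene. The lysosome count lay within the random range near gene ends (5.49), for the upper 4512 peaks (6.25) and outside the most crowded windows (5.71). In attached cells 2 lysosome genes had a peak, ATP6V1A and LAMP1 (75.8).

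SNAP47 encodes a SNARE protein of the SNAP25 family. It spans chromosome 1, 227728168 to 227781226, and held no attached and 2 suspended peaks. The first, at 227735600 to 227735826, had 14 tags, a fold of 9.64 and an FDR of 6.36%, and the second, at 227735999 to 227736302, had 17 tags, a fold of 6.92 and an FDR of 2.75%. Their summits lay 7492 and 8036 bp inside the SNAP47 span, and 358 and 902 bp from an end of JMJD4, a gene within that span, so the position does not tell which gene they belong to. SPIB itself, on chromosome 19, 50418938 to 50431314, had no attached and 1 suspended peak, at 50422716 to 50423109, with 37 tags, a fold of 7.84 and an FDR of 1.68%. Because the cells overexpress SPIB, tags there can also come from the introduced copy.

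**Figure D4:**
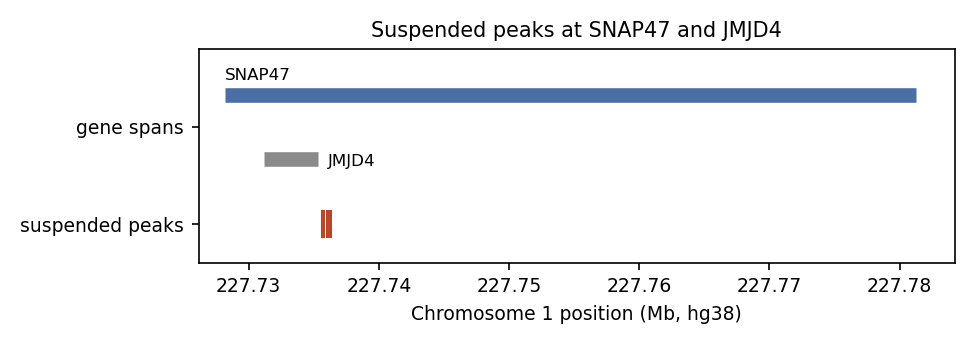
Map of the SNAP47 region on chromosome 1 (x axis, Mb, hg38) with the spans of SNAP47 and JMJD4 and the 2 suspended peaks. Both peaks lie inside SNAP47, just beyond the right-hand end of JMJD4.

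Apoptosis regulators had a peak in 17 of 41 members in suspended cells (percentile 96.7), within the random range, and in 13 for the upper 4512 peaks (98.5) and 16 at an FDR of at most 5% (98.6), both above it. MCL1, an anti-apoptotic BCL2 relative, had the peak with most tags among them, 122 (101.3 to 145.7) at a fold of 8.97, and was also called in attached cells with 51 tags (38.0 to 67.1). The MCL1 peak was called 1460 bp wide in suspended and 460 bp in attached cells, so these tag counts are not like for like. Peaks at a gene end were also found in members such as CFLAR, BAD, APAF1, BCL2L2, PMAIP1 and XIAP, and elsewhere in or within 5 kb of BID, TNFSF10, CASP8 and FASLG. ETS family transcription factor genes had a peak in 14 of 27 members (99.0, random mean 8.22), at the ends of ETV3, ELK4, FEV, ETV6, ETV4 and ERF and elsewhere in or within 5 kb of ELF2, ETV2, ELK3 and FLI1. The ETS count fell within the random range near gene ends (86.6) and outside crowded windows (93.9). ELF1 was the ETS gene with an attached peak.

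Adhesion and lineage genes lay within the random range in suspended cells when all peaks were counted. Here a peak elsewhere lies in the gene or within 5 kb of it. Cell-matrix adhesion genes had a peak in 18 of 45 members (72.7), with ITGAV, ITGA3, ITGA7, VCL and TNS3 at a gene end and ZYX, COL4A2, TNS1 and PTK2 elsewhere. Cell-cell junction and EMT genes had one in 15 of 38 (82.8), with CTNNA1, CLDN4, CLDN7, DSG3, ZEB1, SMAD2, SMAD3 and TGFB1 at a gene end and NTRK2, DSC3, TWIST1 and PKP1 elsewhere. Genes of B cells and plasmacytoid dendritic cells, where SPIB normally acts, had one in 7 of 32 (14.2), with CD40, BTK and CLEC4C at a gene end and PAX5, LYN, POU2F2 and CD79B elsewhere. Squamous and basal epithelium genes had one in 3 of 20 (17.3), namely DSG3, DSC3 and TP63, and in none for the upper 4512 peaks (1.64), below the range. In attached cells TNS3, CIITA and no junction or squamous gene had a peak, all within the random range of the short attached list (percentiles 22.1 to 67.9).

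Genes beside the receptor genes PDGFRA and FGFR1, 2 regions often amplified in lung squamous carcinoma, were included as a check on DNA copies. In suspended cells 9 of 10 genes beside FGFR1 had a peak (99.98), with ASH2L, DDHD2, PLPP5, NSD3 and LETM2 at a gene end and LSM1, PLEKHA2, TACC1 and FGFR1 elsewhere, and so did 6 of 8 beside PDGFRA (98.8), with SCFD2, FIP1L1 and PDGFRA at a gene end and KDR, CHIC2 and LNX1 elsewhere. The PDGFRA count lay within the random range near gene ends (95.8) and for the upper 4512 peaks (85.8). In attached cells NSD3 and LETM2 shared 1 peak of 202 tags. The genes of each region are neighbours that can share peaks, whereas random lists draw from all chromosomes, so the members of these lists are not independent. Olfactory receptor genes are a comparison list of genes silent in most tissues. In suspended cells 5 of 390 members had a peak, against a random mean of 67.2, with OR51M1, OR51B5, OR1L8 and OR1J2 the highest by fold. In attached cells none had one. Neighbours among the olfactory receptor genes are not independent either.

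**Figure D5:**
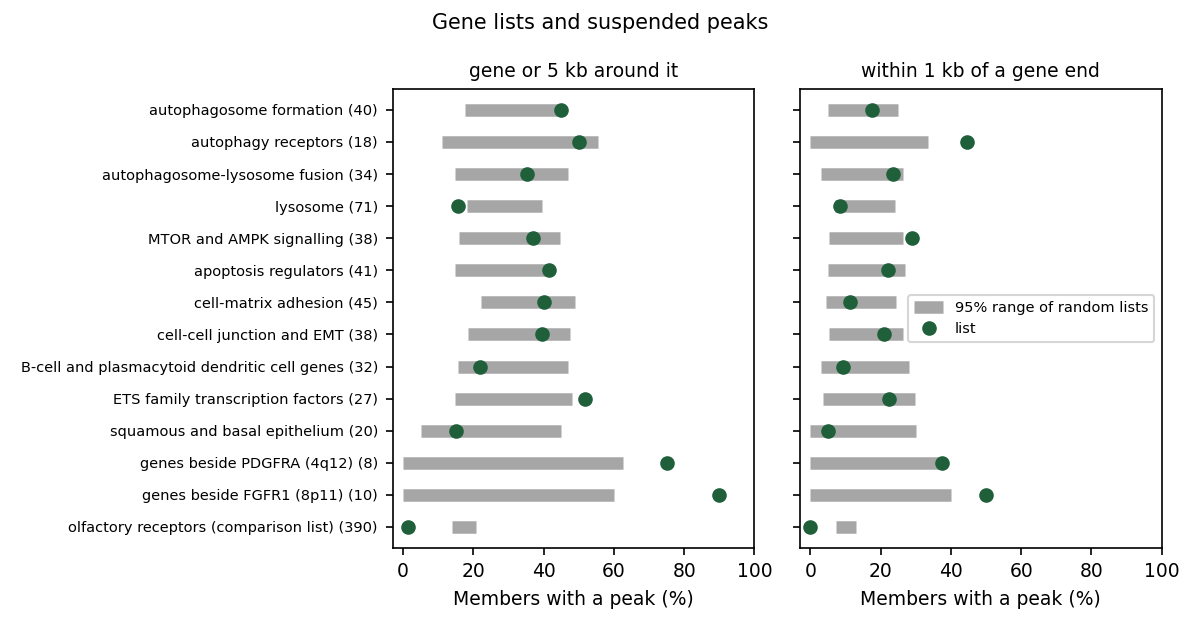
Share of list members with a suspended peak (x axis, percent) in the gene or 5 kb around it (left) and within 1 kb of a gene end (right), for the 14 lists with their number of members. Points are the lists and grey bars the central 95% of random lists, and at gene ends the autophagy receptors lie at 8 of 18 members and the MTOR and AMPK list at 11 of 38, above their bars.

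With 14 lists in 2 conditions, 28 percentiles were computed over the whole gene and another 28 at gene ends. About 1 in 20 would lie outside the central 95% by chance where counts are large enough to reach both sides. For attached lists the central 95% began at 0, except for olfactory receptors over the whole gene. Lists with that lower end could only lie above the range, so the rate does not hold for them. In suspended cells 3 lists lay above the range over the whole gene (ETS factors, and the genes beside PDGFRA and FGFR1) and 2 below it (lysosome and olfactory receptors), and in attached cells 3 lay above (autophagosome formation, MTOR and AMPK signalling, and the genes beside FGFR1) and 1 below (olfactory receptors). At gene ends, 3 suspended lists lay above (autophagy receptors, MTOR and AMPK signalling, and the genes beside FGFR1) and 1 below (olfactory receptors), and 2 attached lists above (MTOR and AMPK signalling, and the genes beside FGFR1) and none below. The attached calls above the range rest on 2 to 4 genes each, most with an FDR of 100%, and over the whole gene none held for the upper 231 peaks. The 2 genes beside FGFR1 among them share 1 peak. Attached autophagosome formation over the whole gene (3 members) only equalled the upper end of the central 95% of random lists. The same holds for attached MTOR and AMPK signalling at gene ends (2 members), and both are called above by their percentile (97.8 each).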

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

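The tests of depth, of a weaker immunoprecipitation, of more SPIB binding and of gene density were chosen only after the result was seen, and the other tests were set down before their values were seen. Peaks on sequences outside chromosomes 1 to 22, X and Y were not used in the comparisons with genes, and they drew attention because they held the most tags of either list. On the unplaced sequence KI270467v1 the attached peak held 354 tags (Poisson 95% interval 318.1 to 392.9, fold 12.6) and the suspended peak 965 tags (905.1 to 1027.9, fold 12.9). In all, such sequences held 9 attached peaks with 5.28% of the tags in peaks and 43 suspended peaks with 1.1%.

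The suspended list was 19.5 times as long as the attached one. A shallower attached ChIP library before scaling is argued against by its depth, 1.016 times that of the suspended one. That ratio cannot decide on the depth behind the calls, because the larger library of each pair was scaled to the smaller one. The smaller library held 15878452 tags in the attached pair (its input) and 20766909 in the suspended pair (its ChIP). A lower depth after scaling in attached cells therefore stays open. A test set down before, the ratio of tags at shared sites (1.36, above its bound of 1.1), was dropped after its value was known, because the called peaks differ in width. Per bp the ratio was 1.104. Where the suspended peak was no wider, the ratio of tags was 0.987, but 1.19 per bp (1.11 to 1.31) at those same sites. All 37 attached peaks with an FDR of at most 10% (100%) were in the suspended list, which a weaker immunoprecipitation from attached cells needs. It also needs fewer tags at shared sites in the attached library. At sites of similar width the ratio was 1.19 (1.12 to 1.28), above the bound of 1.1. Per bp it was 1.13 (1.08 to 1.18), an interval that spans this bound. The per-bp condition was added after both ratios were seen, and by tags alone the bound was met. Only the 0.987 did not lie above 1, so a fall was seen in the other ratios, but its size depends on how width is treated. A weaker immunoprecipitation and more SPIB binding in suspended cells cannot be told apart with 1 ChIP library per condition. The smaller attached input, and the lower depth after scaling to it, stay open too.

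Strong suspended peaks were shared more often than weak ones (24.6% of the top 5% by score against 0.377% of the lower 4512), and several of the shared sites of highest fold lay in or near neuronal genes. Many ChIP experiments pull down heavily transcribed short genes. Of these, tRNA, ribosomal protein and histone genes are argued against, since 0.485% of the common sites (upper bound 2.67%) lay within 1 kb of a tRNA gene or an end of a ribosomal protein or histone gene. Other short genes were not counted, among them the small nuclear RNA genes RNVU1-27 and RNVU1-31, which had common sites in or within 5 kb. A candidate explanation is that these are binding sites of REST, the repressor of neuronal genes in other tissues. Of 60 known REST targets, chosen after the neuronal genes were noticed and without those already seen beside strong peaks, 18 held a common peak, at percentile 100 of random lists (mean 0.649), against 0 of 28 glial genes. The list holds neuronal genes and no list of other neuronal genes was tested, so it cannot tell REST sites from neuronal genes in general. Whether SPIB shares these sites with REST, binds neuronal genes without it, or the antibody enriches them without SPIB stays open. No cells without tagged SPIB and no motif search were used here.

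Peaks crowded into some regions, with 31 of 612 windows of 5 Mb, picked on the suspended list, holding 1877 suspended peaks (20.9%) and 84 attached ones (18.5%). The density of annotated genes alone is argued against by windows picked as crowded on 1 random part of the peaks. They held 2.43 times as many of the other peaks per gene end as the remaining windows (2.07 to 2.84). Over 100 such splits this ratio ran from 2.03 to 2.52. Gene ends were those of all annotated genes and gene activity was not measured, so the density of active genes was not tested. More DNA copies may contribute. The background implied by tags, width and fold was 1.55 times as high in crowded windows (1.502 to 1.59), and 1.60 times for peaks away from gene ends. Around FGFR1, within 1 Mb on either side, 51 peaks had a background 2.45 times the genome's median (interquartile range 2.16 to 3.32). Around PDGFRA 16 peaks had 1.97 times, with a wider interquartile range (0.939 to 2.67) that reaches below the genome's median. Copy number was not measured, so a regional change in SPIB binding was not tested apart from it.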

How the results depend on the processing

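Limits on the authors' FDR, locally moved peaks, the treatment of peak width at shared sites and lists without crowded windows were chosen after seeing the data. Lists without crowded windows at first lost the peaks there alone, and after those values were seen the genes there were left out too, which took the attached olfactory receptors from 3.04, inside the random range, to 2.2, below it. No paired analysis was possible because each group had 1 library and the labels give no replicate numbers, and for the same reason no library could be left out. The motif search and its 4 alternatives were not run, since no genome sequence was used here. Of 252 alternative values 184 stayed within their bounds and 68 moved, 35 of them for the values that answer a comparison, and where no cause follows from the alternative itself the cause was not tested. None of the 14 lists outside the random range went to its opposite side, but percentiles inside it crossed the chance value of 50, such as MTOR and AMPK signalling in suspended cells, from 80.4 to 33.8 without crowded windows. Keeping the higher-scoring peaks of each list left 231 attached and 4512 suspended by construction, with an overlap of 62.8% and gene-end shares of 43.5% (attached) and 46.0% (suspended), the opposite order to the full lists. An FDR of at most 5% left 25 attached peaks, a ratio between the lists of 277.3, an overlap of 100% and gene-end shares of 47.8% and 39.8%. Cutting the suspended list to the attached length gave an overlap of 24.0% and a suspended gene-end share of 64.7%. A distance of 3 kb gave shares of 48.3% (attached) and 49.0% (suspended), and protein-coding genes alone 30.7% and 29.4%. Against the same peaks moved by 20 to 200 kb, the observed gene-end shares were 4.17 (attached) and 3.62 (suspended) times as high. The tag ratio at shared sites fell to 1.104 per bp, 1.19 at sites of similar peak width and 0.987 where the suspended peak was no wider. Per bp that last ratio was 1.19 (1.11 to 1.31). Attached lists above the random range fell from 3 to 0 with the higher-scoring peaks, 0 at an FDR of at most 5% and 1 without crowded windows, and those below from 1 to 0 near gene ends, 0 with the higher-scoring peaks and 0 at an FDR of at most 5%. Suspended lists above the range went from 3 to 5 at an FDR of at most 5% and 1 without crowded windows, and those below from 2 to 1 near gene ends and 1 without crowded windows, where none of the 10 genes beside FGFR1 is left. Near gene ends without crowded windows, attached lists above and below the range numbered 0 and 0, and suspended lists 1 and 1. A median of 18 tags per attached peak limits what can be said of any single site.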

Other observations

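Gene families, chosen after seeing the data by their symbols, differed in how often they held a suspended peak, and each is given with its random mean and percentile over the whole gene. Ribosomal protein genes lay above the central 95% of random lists, with a peak in 31 of 73 cytoplasmic members (mean 15.2, percentile above 99.9), 24 of them within 1 kb of a gene end (mean 9.25), and in 28 of 74 mitochondrial members (17.8, percentile 99.6), 22 at a gene end (9.99). Histone genes, with 16 of 73 members (8.52, percentile 99.4), also lay above it. Translation initiation factor genes had a peak in 19 of 56 members (15.7, percentile 84.3), proteasome genes in 15 of 48 (12.5, percentile 79.3) and NADH dehydrogenase genes in 8 of 36 (9.10, percentile 34.9), all within the range over the whole gene. At a gene end, initiation factor genes had one in 14 members (8.25, percentile 97.8) and histone genes in 10 (4.90, percentile 98.6), both above the range, and proteasome genes in 10 (6.81, percentile 89.6) and NADH dehydrogenase genes in 4 (5.20, percentile 30.5), within it. The initiation factor count only equalled the upper end of the central 95% of random lists. Zinc finger genes with ZNF symbols had one in 159 of 509 members (146.4, percentile 89.6), within the range, and at a gene end in 104 (77.5, percentile 99.9), above it. In attached cells the cytoplasmic ribosomal protein, histone, proteasome and NADH dehydrogenase lists held none, translation initiation factors and mitochondrial ribosomal proteins 1 each, and ZNF genes 8. With random means of 0.467 to 1.07 for all but the ZNF list (8.73), each of these lay within the random range.

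HOX genes had a suspended peak in 15 of 39 members (random mean 8.03, percentile 99.5), above the range, and none within 1 kb of a gene end (4.78, percentile 0.32), below it. Keratin genes had one in 7 of 55 members (12.5, percentile 2.92), within the random range, and none at a gene end (7.49), below it. Clustered protocadherin genes had one in 2 of 53 members (17.3), and both were at a gene end (6.95, percentile 1.39), below the range in both counts. Collagen genes had one in 13 of 44 members (16.8, percentile 11.5) and 2 at a gene end (5.84, percentile 3.48), and solute carrier genes in 102 of 347 (105.5, percentile 33.9) and 45 at a gene end (51.0, percentile 17.8), all within the range. Clustered families share neighbours and peaks, so their members are not independent. In attached cells the HOX, keratin and protocadherin lists held none, collagen 1 and solute carriers 8, all within the random range (percentiles 14.5 to 69.3).

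The REST target list also followed peak strength in the suspended list. Of its 60 members 28 held a peak with an FDR of at most 1% (random mean 4.59), and 13 held one among the lower-scoring 4512 peaks (10.5, percentile 80.6). Members with a common peak included BDNF, VGF, CHGB, SCG3, STMN3 and SYT7.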
